A study of Mus musculus with 4 samples.

How the data were processed

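Total RNA of mouse DFAT cells was hybridised to 4 single-colour Affymetrix mouse arrays, 1 each for DMSO, Y-27632, control siRNA and Mkl1 siRNA, with groups taken from the sample labels. The deposited values are log2 signals, 1 per probe set and array, made by the authors with RMA per the submitters' processing notes. RMA corrects background, quantile-normalises arrays and summarises probes into probe sets; its version, the chip definition and the set of arrays normalised together are not given in the sources used here. The log2 scale was read from the values, which ran from 2.02 to 14.6, and genes were not centred. No scanner files were used here, so the scale could not be set against raw signals. The array medians were 5.71 (DMSO), 5.67 (Y-27632), 5.69 (control siRNA) and 5.70 (Mkl1 siRNA), and arrays differed by at most 0.111 at the same rank. RMA compresses differences near background, so ratios of weak genes may be too small, and quantile normalisation hides any difference in total RNA per cell. Pearson correlations between arrays over probe sets ran from 0.987 to 0.995.

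Probe sets were named through the platform annotation: of 45101 probe sets, 34958 had 1 gene symbol, 932 several and 9211 none. Only those with 1 symbol were given a gene name. The gene numbers of 34754 were found in a reference gene table of assembly GRCm38.p6, used for names only, and 204 kept the platform symbol. Mkl1 is listed as Mrtfa, Mkl2 as Mrtfb and the older names Ctgf and Cyr61 as Ccn2 and Ccn1. The 64 control probe sets were left out of gene values. For each of 18193 genes the probe set with the highest mean over the 4 arrays was used, and 11600 genes whose highest array reached the median of all values (5.69) were analysed. Of genes with several probe sets and a difference of at least 2-fold, all probe sets pointed the same way in 73 of 92 with Y-27632, 171 of 219 with Mkl1 siRNA and 112 of 123 between the controls.

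With 1 array per group no test, leave-one-out or other split of the arrays was possible, so no p-values are given. Differences were computed for Y-27632 minus DMSO, Mkl1 siRNA minus control siRNA and, as background, control siRNA minus DMSO, and genes were counted from 2-fold (1 on the log2 scale). Shared genes were set beside the number expected for independent lists. The first pair of comparisons shares no array; the background comparison shares 1 array with each of them, so no correlation with it is given. There were 26 gene lists; for the 22 with at least 5 measured genes, the median was ranked among 10000 random lists of the same size drawn from 20 bins of mean level. A 95% range is the mean of the random medians plus or minus 1.96 SD. These ranks describe these arrays and are no test of the treatments.

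Gene lists, the rule for named genes, the filter, the threshold and all alternatives except those with the other control array were fixed before the data were examined. The lists were targets of MRTF-SRF, YAP-TAZ and p53, smooth muscle and immediate early genes, mature adipocyte genes, early regulators and inhibitors of adipogenesis, and brown and beige adipocyte genes. Further lists covered fatty acid and cholesterol synthesis, extracellular matrix, TGF-beta response, focal adhesion, S phase, G2 and mitosis, interferon response, inflammatory cytokines, unfolded protein and amino acid stress, heat shock, and hypoxia and glycolysis. Markers of osteoblasts, chondrocytes, skeletal myoblasts, endothelial cells and macrophages or leukocytes stood for other cell types. Some members, such as Plin1, Cfd and Runx2, were not analysed here, and 1 further list fixed at the same time is not reported here. Named genes were the 10 highest and 10 lowest of each treatment comparison with no more probe sets against that direction than in it, the 6 furthest in the same direction in both, up to 4 members per list, and Mkl1, Mkl2, Srf, Pparg, Cebpa, Fabp4, Acta2, Actb, Actg1, Gapdh and Ppia. Gapdh was read only by control probe sets, which differed by -0.15 to -0.05 with Y-27632 and by -0.29 to -0.26 with Mkl1 siRNA, and Ppia was not analysed here. Genes named outside this rule are the control-array differences, the 11 genes with opposite differences and the families in the closing section, all chosen after their values were seen.

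Alternatives were the mean of all probe sets of a gene, leaving out probe sets whose names end in _s_at, _x_at or _a_at, no filter, a filter at the 75th percentile (8.08), loess of the difference on the mean level (span 0.3), subtracting the median difference, a 1.5-fold threshold, the 99th percentile of the control arrays' difference as threshold, and the other control array. Such names mark probe sets that may bind several transcripts, of the same gene or of others. The calculations were tested on simulated data. For Y-27632 against DMSO, 4.5% of 200 unchanged lists of 20 genes fell outside the 2.5th to 97.5th percentiles and all 100 lists shifted by 0.5 were found. The unchanged lists were random genes from the same differences, so a small share outside was fixed in advance. Lists of genes that vary together, and shifts below 0.5, were not simulated. Such lists can leave the range between the controls too, as interferon genes did at a median of -0.72 (random range -0.12 to 0.12). With noise taken from both control arrays, a difference of at least 2-fold was called in 46.0% of genes planted at 2-fold, 96.0% at 4-fold and 2.04% of unchanged genes. That noise was the control siRNA minus DMSO difference, shuffled among genes of similar level. The rate in unchanged genes therefore repeats the share called between the controls, 111 higher and 126 lower of 11600. It is no rate of false calls between replicates, because these controls also differ by transfection. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.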

Results

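Gene expression was measured in mouse DFAT cells, fibroblast-like cells obtained when mature fat cells lose their lipid and de-differentiate in culture. The cells were treated with the solvent DMSO or with Y-27632, a small-molecule inhibitor of the ROCK kinases that promote actomyosin contraction, or were transfected with a control siRNA or an siRNA against Mkl1. Mkl1, listed here under its present symbol Mrtfa, encodes an actin-binding coactivator of the transcription factor SRF. The sample labels give no dose, duration or culture medium, and do not say whether the cells were kept in conditions that promote fat cell formation. Each of the 4 groups had 1 array, so no difference has a replicate check, no p-value can be given, and the number of arrays limits the precision. Differences are log2 RMA signal, treatment minus its own control, and a gene was counted from a 2-fold difference upward among 11600 measured genes. The difference between both control arrays, measured the same way, served as background: 111 genes were at least 2-fold higher and 126 at least 2-fold lower with control siRNA than with DMSO. The largest of these control differences were Lum at -4.28, Scara5 at -3.53 and Plac8 at -3.31, and Car8 at 3.41, Il1rn at 3.40 and Tnfrsf11b at 3.33.

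The targeted transcript Mrtfa, read by 1 probe set, had a log2 signal of 8.55 with control siRNA and 7.70 with Mkl1 siRNA, a difference of -0.85 or a ratio of 0.554. Its signal was 8.32 with DMSO and 8.18 with Y-27632. Its relative Mrtfb differed by 0.05 with the siRNA and by -0.22 with Y-27632. Srf differed by -0.49 and -0.21.

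The first comparison asked how expression in DFAT cells differed after ROCK inhibition. With Y-27632, fat cell genes stood far above the DMSO array. Adipoq, which encodes the fat cell hormone adiponectin, was higher by 3.55, from 10.14 to 13.69, a ratio of 11.7. Adig (adipogenin) was higher by 3.59, Retn (the secreted protein resistin) by 3.53, Cd36 (a fatty acid transporter) by 3.37, Dgat2 (which makes triglyceride) by 3.33 and Cidec (a lipid droplet protein) by 3.18. The 3 Cd36 probe sets ran from 2.003 to 3.70, and the 2 of Dgat2 stood at 2.51 and 3.33. Lcn2, an iron-siderophore-binding lipocalin, was the highest at 4.28, followed by Wfdc21 at 4.01, Rgcc, a regulator of the cell cycle, at 3.64 and Hp, the haemoglobin-binding protein haptoglobin, at 3.63. For Lcn2 and Hp the control siRNA array also stood above DMSO, by 1.82 and 2.75. In total 147 genes were at least 2-fold higher and 26 at least 2-fold lower. Of the 147 higher genes, 98 were also at least 2-fold above the control siRNA array.

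The 10 genes furthest below DMSO included Rassf6 at -1.85, Cemip, which takes part in hyaluronan breakdown, at -1.68, Siglecg, a sialic-acid-binding receptor, at -1.67, and Slc1a6, a glutamate transporter, at -1.48. The interferon-induced gene Oas3 differed by -1.48, Ptchd4 by -1.46, Sprr1a by -1.45, Gm30873 by -1.43, Fgd3 by -1.41, and Ccn2, which encodes the matrix protein known as connective tissue growth factor, by -1.43. Of the 26 lower genes, 10 were also at least 2-fold below the control siRNA array. The control siRNA array was itself at least 2-fold below DMSO for 6 of the 10 genes furthest below DMSO, with Slc1a6 at -2.64, Oas3 at -2.10, Sprr1a at -2.10, Cemip at -1.76, Ptchd4 at -1.35 and Gm30873 at -1.21, and the first 4 of them were higher with Y-27632 than with control siRNA. The 3 Cemip probe sets ran from -1.68 to -0.07 and the 3 of Fgd3 from -1.41 to 0.07, and with the mean of all probe sets Cemip stood at -0.72 and Fgd3 at -0.60, short of 2-fold.

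All 17 measured members of the mature adipocyte list were above DMSO with Y-27632, 14 of them at least 2-fold, and the list median of 1.40 exceeded the medians of all 10000 random lists matched on level. Pparg, the nuclear receptor that drives fat cell formation, was higher by 1.23 and its partner Cebpa by 1.11, or by 0.93 and 0.53 against control siRNA. The fatty acid carrier Fabp4 was higher by 1.40, and its 4 probe sets ranged from 1.37 to 1.89. The same list had a median of -0.05 between the control arrays. As a sign of RNA composition, the control probe sets for 18S ribosomal RNA were lower by a median of -0.48 with Y-27632 and -0.49 with Mkl1 siRNA, against 0.15 between the controls. The 3' minus 5' difference of Actb was 0.255 with Y-27632 and 0.145 with Mkl1 siRNA, and that of the pyruvate carboxylase control probe sets was 1.64 and 1.77, where the 3' signal was higher by 1.77 and 2.10 and the 5' signal by 0.13 and 0.33.

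Other fat-related lists differed less. Among early adipogenic regulators, 14 of 17 were above DMSO (median 0.18, percentile 99.9), with Klf15 at 1.03 and the preadipocyte factor Zfp423 at 0.82, but against control siRNA the median was 0.12, inside the range of random lists. Fatty acid synthesis genes had a median of 0.30 with 11 of 14 above 0. In that list Scd1, the stearoyl-CoA desaturase, was higher by 1.83, Thrsp by 1.77 and Fasn, the fatty acid synthase, by 0.88; the 3 Thrsp probe sets ran from 0.08 to 4.28. The 5 measured brown and beige adipocyte genes had a median of 0.34, with Ppargc1b, a transcriptional coactivator, at 1.85 and Cox7a1 at 0.60. Without the filter on low values that median was 0.06. Inhibitors of adipogenesis had a median of 0.08 with 10 of 16 above 0, Wnt5a at 1.07 and Gata3 at -0.50, and the median was 0.20 against control siRNA. Cholesterol synthesis genes had a median of 0.01 with 9 of 17 above 0, and Insig1, which restrains sterol synthesis, was higher by 1.33, while the median was -0.18 against control siRNA.

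Targets of MRTF and SRF, many of which encode actin and contractile proteins, lay below DMSO in 31 of 32 cases with a median of -0.30, lower than in any of the 10000 random lists. Ccn2 differed by -1.43, the actin-binding proteins Tagln (transgelin) by -1.25 and Cnn1 (calponin) by -1.21, and Fhl1 by -0.96. Acta2, smooth muscle actin, differed by -0.59, and its 3 probe sets ran from -1.36 to -0.59, while the cytoplasmic actins Actb and Actg1 differed by -0.14 and -0.17. Mylk, the kinase that phosphorylates myosin light chain, was the exception in this list at 0.58, with 3 probe sets from 0.05 to 0.66. The smooth muscle list, which shares 5 genes with this list, had a median of -0.08 with 5 of 9 below 0, or -0.39 without probe sets that may bind several transcripts. Targets of YAP and TAZ, coactivators that respond to cell tension, had a median of -0.16 with 15 of 21 below 0, led by Ccn2, Ankrd1 at -1.21, Crim1 at -0.96 and Amotl2 at -0.74, and against control siRNA the median was -0.29.

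The extracellular matrix list lay within the range of random lists with Y-27632, with a median of 0.05 and 23 of 36 above 0; the proteoglycan Lum was higher by 2.08 and Fbln1 by 1.04, while Fbln5 differed by -0.96. TGF-beta response genes had a median of 0.07 with 11 of 17 above 0, Tgfbi at 0.96 and Tgfbr1 at 0.74, and the median was -0.11 against control siRNA. Focal adhesion and integrin genes lay below the range of random lists (-0.07 to 0.10), with a median of -0.10 and 16 of 22 below 0, including Vcl (vinculin) at -0.54 and Itgb1 at -0.46, while Itga6 was higher by 0.93; without probe sets that may bind several transcripts the median was -0.23. Immediate early genes had a median of -0.08 with 9 of 16 below 0, although the zinc-finger factors Egr3 and Egr2 were higher by 1.56 and 1.55. Control siRNA stood above DMSO for them by 1.87 and 0.999, and against control siRNA Egr3 lay on the other side of 0 at -0.31 and Egr2 stood at 0.55. The 2 Egr3 probe sets differed in sign, at -0.22 and 1.56. With the mean of all probe sets Egr3 stood at 0.67, Wnt5a at 0.84 and Fbln1 at 0.75, short of 2-fold, and Acta2 at -1.04, past it.

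Cell division and interferon genes were low with Y-27632 relative to DMSO but not relative to control siRNA. All 25 G2 and mitosis genes were below DMSO (median -0.42), among them Cdc20 at -0.65, Mki67 at -0.61, Anln at -0.60 and the mitotic kinase Plk1 at -0.59. Of 20 S phase genes, 16 were below DMSO (median -0.35), with the replication helicase subunits Mcm5 at -0.71 and Mcm6 at -0.61. All 25 interferon response genes were below DMSO (median -0.53), with Irf7, a regulator of interferon genes, at -1.11, the antiviral synthase Oas1a at -0.93 and Usp18 at -0.87. The control siRNA array was itself below DMSO for these lists, with medians of -0.42, -0.27 and -0.72. Against control siRNA the Y-27632 medians were -0.07 for G2 and mitosis, -0.06 for S phase and 0.07 for interferon genes, each inside the range of random lists.

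Among inflammatory cytokine genes the median was -0.05 while the mean was 0.34, because Lcn2, the serum amyloid Saa3 at 2.71 and the alarmin Il33 at 1.20 were higher whereas 9 of 15 were below 0. Hypoxia and glycolysis genes had a median of 0.11 with 10 of 15 above 0, led by Pfkfb3, which drives glycolysis, at 2.15 on 1 probe set and -0.02 on the other, and the median was 0.46 against control siRNA. Stress genes of the unfolded protein and amino acid response had a median of -0.04, with Chac1 at -0.60 and Dnajb9 at 0.50, and the median was 0.38 against control siRNA. For the hypoxia and stress lists control siRNA was itself below DMSO, by medians of -0.25 and -0.46. The p53 target list had a median of 0.08 with Plk2 at -0.46, and heat shock genes had a median of -0.02 with Hspb1 at -0.53. Markers of other cell types were few above the filter: 5 chondrocyte genes had a median of -0.13, 3 skeletal myoblast genes -0.17, 4 endothelial genes -0.23, 4 macrophage and leukocyte genes -0.17, and the single osteoblast gene Sp7 differed by -0.29. Further named genes at least 2-fold from DMSO were short of 2-fold against control siRNA, with Hp at 0.89, Fbln1 at 0.17, Siglecg at -0.89, Cnn1 at -0.81, Ankrd1 at -0.63 and Irf7 at 0.07.

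**Figure D1:**
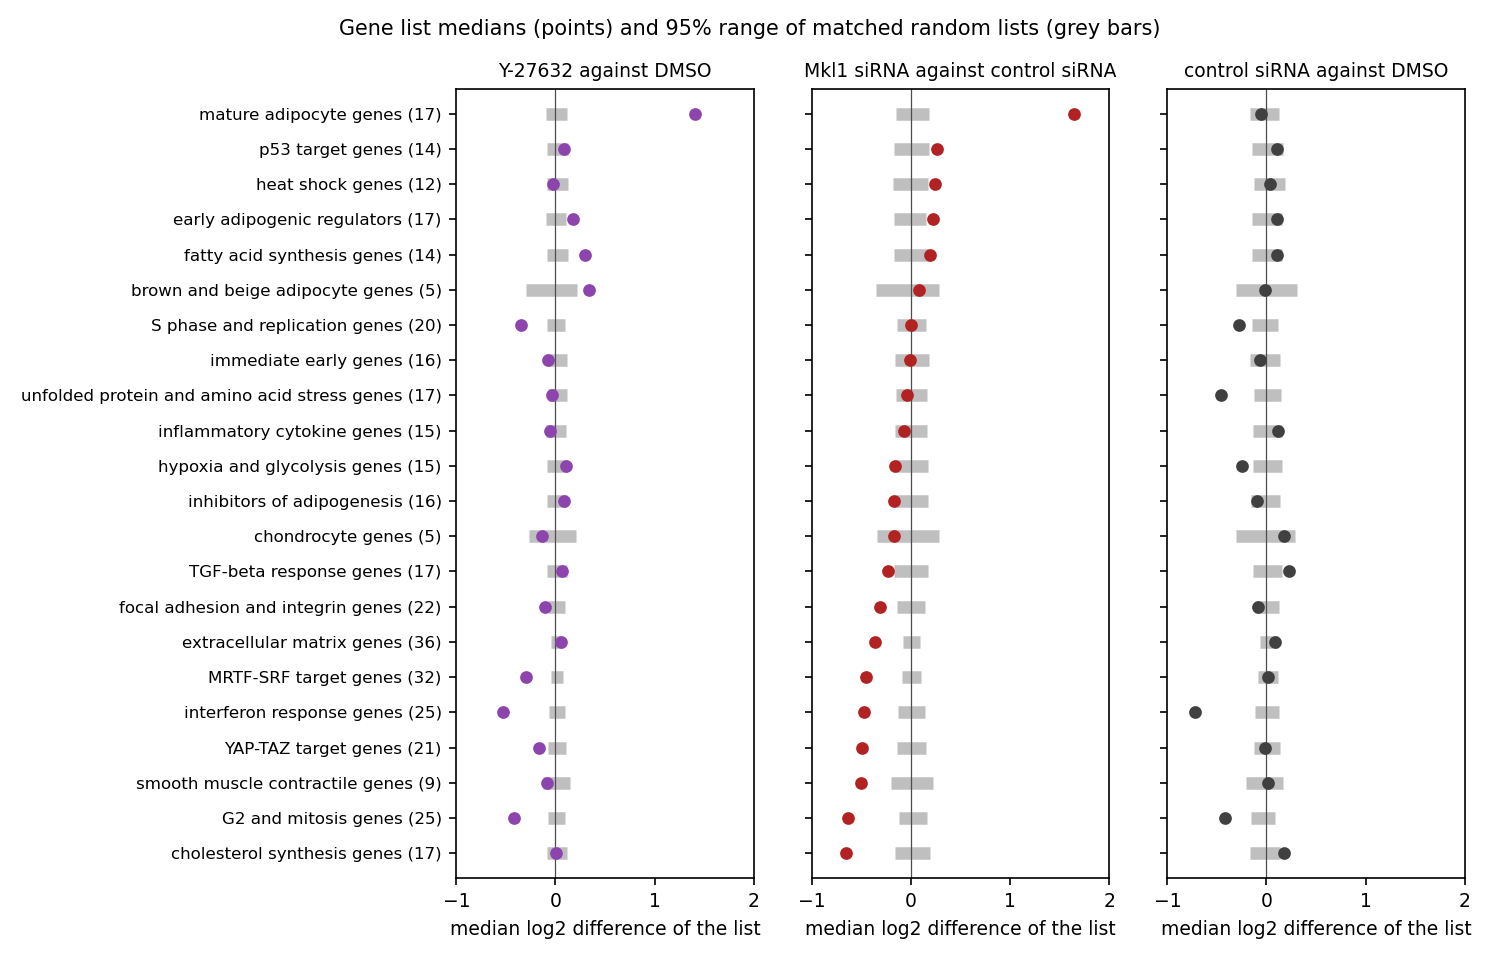
Median log2 difference of each list with at least 5 measured genes (points; number of measured genes in parentheses) and the 95% range of 10000 random lists matched on level (grey bars), for 3 comparisons of 1 array with 1 array. Mature adipocyte genes stood at 1.40 with Y-27632 and 1.65 with Mkl1 siRNA, against -0.05 between the controls.

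The second comparison asked how expression differed after Mkl1 knockdown. Fat cell genes again stood on the higher side. Aldh1a7, an aldehyde dehydrogenase, was higher by 4.14 than with control siRNA, Rgcc by 4.04, Adipoq by 3.83, the fat cell galectin Lgals12 by 3.66 and the carbonic anhydrase Car3 by 3.64. Gpat3, an enzyme of triglyceride synthesis, was higher by 3.57, Adig by 3.51, the aldehyde oxidase Aox3 by 3.48, Fcor by 3.34 and Cidec by 3.30. Probe sets disagreed for Lgals12, at 0.35 and 3.66 with a mean of 2.01, and for Car3, where 4 ran from -0.01 to 3.64. For Aldh1a7 and Gpat3 the control siRNA array was below DMSO by -2.35 and -1.12. In total 208 genes were at least 2-fold higher and 202 at least 2-fold lower. Of the 208 higher genes, 165 were also at least 2-fold above the DMSO array.

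The chemokines Ccl8 and Ccl11 differed by -4.27 and -3.57, from log2 signals of 10.82 and 12.72 with control siRNA, and Cxcl10, an interferon-induced chemokine, by -2.50. The protease inhibitor Serpinb2 differed by -3.15, Clca2 by -3.41, Pbp2 by -2.53, the membrane peptidase Mme by -2.50, the calcification inhibitor Mgp by -2.40 and the superoxide-producing oxidase Nox4 by -2.24. The neuropeptide Y receptor Npy1r differed by -2.36 on 1 probe set and by 0.68 on the other, with a mean of -0.84. The second probe sets of Mme and Nox4 stood at -1.23 and -1.58. The control siRNA array stood above DMSO for Mgp by 2.81, Ccl11 by 2.08, Nox4 by 2.02, Clca2 by 1.39, Mme by 1.14 and Ccl8 by 1.13, and below it for Serpinb2 by -1.01. Of the 202 lower genes, 114 were also at least 2-fold below the DMSO array.

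All 17 mature adipocyte genes were above control siRNA, 14 of them at least 2-fold, with a median of 1.65 that exceeded all random lists. Pparg was higher by 1.86, Cebpa by 1.45 and Fabp4 by 1.59, and the 4 Fabp4 probe sets ran from 1.38 to 3.07. Early adipogenic regulators had a median of 0.22 with 10 of 17 above 0, including Zfp423 at 1.35 and Klf15 at 1.01, but Klf15 was lower with control siRNA than with DMSO, by -0.97, and differed by 0.04 between Mkl1 siRNA and DMSO. Inhibitors of adipogenesis had a median of -0.17 with 10 of 16 below 0, including the transcription factors Sox9 at -1.05 and Gata3 at -0.99; 1 of the Sox9 probe sets stood at 0.06, and against DMSO the median was -0.09, inside the random range. Fatty acid synthesis genes had a median of 0.19 with 11 of 14 above 0, Thrsp at 1.75 (3 probe sets from 0.07 to 5.19), Scd1 at 1.55 and the elongase Elovl6 at -0.93, and the median was 0.46 against DMSO. The brown and beige list had a median of 0.09, with Ppargc1b at 3.17 and Cox7a1 at -1.20.

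MRTF-SRF targets lay below control siRNA in 29 of 32 cases with a median of -0.46, lower than in any random list. Fhl2 differed by -1.39, the myosin light chain Myl9 by -1.09, tropomyosin Tpm2 by -0.98, Tagln by -0.96 and Acta2 by -0.54, while Mylk was higher by 1.03. The 3 Acta2 probe sets ran from -1.69 to -0.54, with a mean of -1.01, and Acta2 stood at -1.69 without probe sets that may bind several transcripts. Leaving out such probe sets moved the list median to -0.30. Of 9 smooth muscle genes, 8 were below 0 (median -0.51), with smoothelin (Smtn) at -1.08 and Lmod1 at -0.76, and without the filter on low values the median was -0.23. YAP-TAZ targets had a median of -0.49 with 19 of 21 below 0, including Ankrd1 at -1.82, the receptor kinase Axl at -1.07, Ccn2 at -0.93 and Dock5 at -0.75. Actb and Actg1 differed by -0.05 and -0.29.

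Matrix, adhesion and sterol genes were low with Mkl1 siRNA. Of 36 extracellular matrix genes, 32 were below 0 (median -0.36), among them the metalloproteinase inhibitors Timp3 at -1.81 and Timp1 at -1.27, Col8a1 at -1.40 and the adhesion-modulating glycoprotein Tnc at -1.37. Focal adhesion and integrin genes had a median of -0.32 with 18 of 22 below 0, Itgb3 at -1.09, Itga5 at -0.82 and Itga6 at 0.93. TGF-beta response genes had a median of -0.23 with 11 of 17 below 0, Inhba at -1.20 and Bhlhe40 at -0.99, while Id1 was the only member at least 2-fold higher, at 1.001, but the median was -0.07 against DMSO. Cholesterol synthesis genes had a median of -0.65 with 15 of 17 below 0. In that list Msmo1 differed by -1.47, Hsd17b7 by -1.40, Idi1 by -1.19 and Cyp51 by -1.16, while Dhcr7 was higher by 0.95. Against DMSO this median was -0.27, and control siRNA stood above DMSO by a median of 0.18. For Hsd17b7 control siRNA was above DMSO by 2.19, so that Mkl1 siRNA was higher than DMSO by 0.78, and against DMSO Msmo1 stood at -0.92, Idi1 at -0.18 and Cyp51 at -0.95.

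All 25 G2 and mitosis genes were below control siRNA (median -0.64), with Ccnb2, a mitotic cyclin, at -1.04, Kif23 at -1.03 and Aspm at -1.02, and against DMSO the median was -1.07. S phase genes had a median of -0.00 with 10 of 20 below 0, Prim1 at 0.53 and Gins2 at -0.44, and the median was -0.19 against DMSO. Of 25 interferon response genes, 24 were below control siRNA (median -0.48) and 8 at least 2-fold, including Cxcl10, Ifit3 at -1.86, the antiviral gene Rsad2 at -1.66 and the GTPase Gbp2 at -1.60. Against DMSO the interferon median was -1.35. The inflammatory list had a median of -0.07, with the monocyte chemokines Ccl2 at -1.67 and Ccl7 at -1.28 and Il33 at -1.67, but Lcn2 at 2.27.

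The p53 target list had a median of 0.26 with 10 of 14 above 0, including Trp53inp1 at 0.68 and Btg2 at 0.63, and the median was 0.40 against DMSO. Heat shock genes had a median of 0.24 with 10 of 12 above 0, the mitochondrial chaperone Hspd1 at 0.65, Hspa1a at -1.16 and Cryab at -0.68. Stress genes of the unfolded protein response had a median of -0.04 with Atf5 at -0.92 and Nupr1 at -0.76, and the median was -0.90 against DMSO. Hypoxia and glycolysis genes had a median of -0.16 with Pfkfb3 at 2.42 on 1 probe set and -0.06 on the other and Ero1a at -0.87, and the median was -0.52 against DMSO. Control siRNA was itself below DMSO, by medians of -0.46 for the stress list and -0.25 for the hypoxia list. Immediate early genes had a median of -0.01, with Egr2 at -1.03 and Nr4a1 at 0.62. The 5 chondrocyte genes had a median of -0.17 with Col11a1 at -1.84. Skeletal myoblast, endothelial, and macrophage and leukocyte genes had medians of -0.01, 0.06 and -0.09, and Sp7 differed by 0.03. Against DMSO, Mgp stood at 0.41, and further named genes were short of 2-fold, with Ccl2 at -0.94, Ccl7 at -0.33, Nox4 at -0.22, Egr2 at -0.04, Itgb3 at -0.16, Inhba at -0.83, Timp1 at -0.65, Fhl2 and Myl9 at -0.82, Cox7a1 at -0.96 and Hspa1a at -0.99. With the mean of all probe sets, 8 named list members stood short of 2-fold: Msmo1 at -0.99, Mylk at 0.73, Itgb3 at -0.72, Inhba at -0.70, Sox9 at -0.69, Kif23 at -0.56, Axl at -0.54 and Aspm at -0.50.

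**Figure D2:**
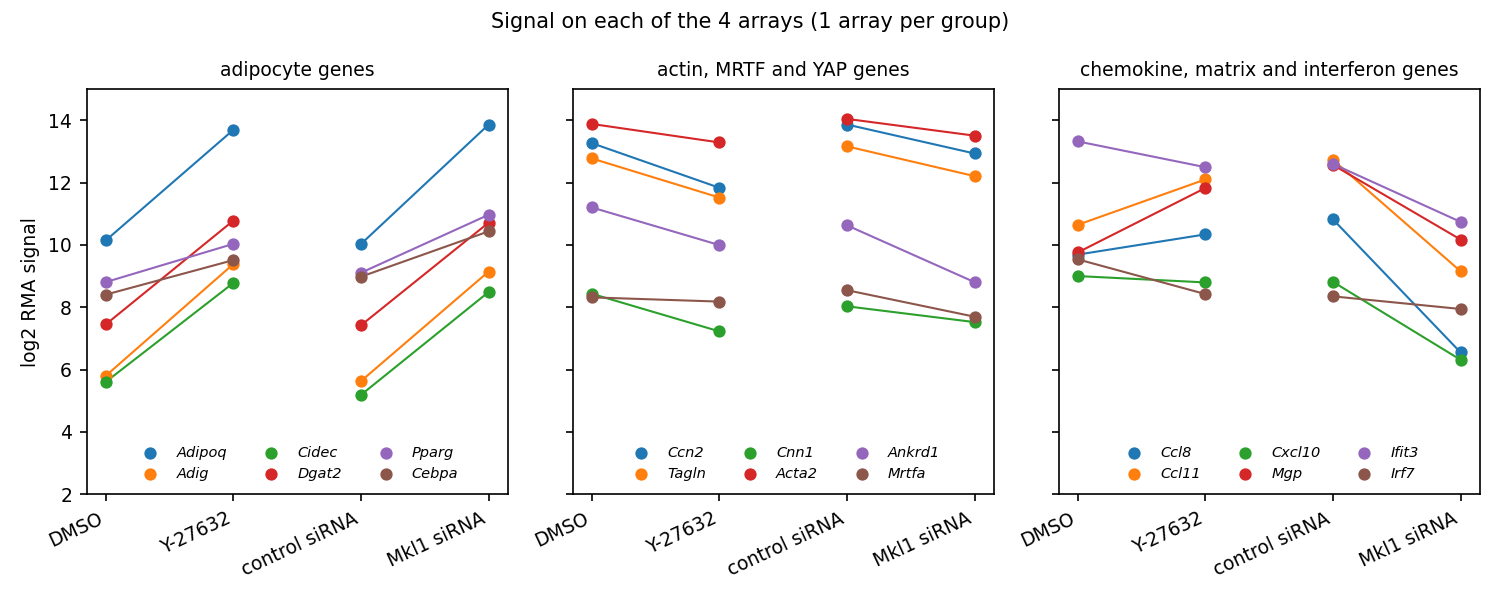
Log2 RMA signal of 18 named genes on each of the 4 arrays (1 array per group), with lines joining each treatment to its own control. Adipoq stood at 10.14 with DMSO and 13.69 with Y-27632, and at 10.03 with control siRNA and 13.86 with Mkl1 siRNA.

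The third comparison set both treatments side by side, each against its own control, so that no array was shared. Fat cell genes stood at the top of the shared set with Rgcc and Wfdc21: Rgcc, Adipoq, Adig, Dgat2, Wfdc21 and Cidec were each higher by more than 3 in both, with Dgat2 at 3.33 and 3.29 and Wfdc21 at 4.01 and 3.24. In all, 82 genes were at least 2-fold higher in both comparisons, where independent lists of these lengths would share 2.64. They were 55.8% of the genes higher with Y-27632 and 39.4% of those higher with Mkl1 siRNA. Only 5 genes were at least 2-fold lower in both, against 0.453 for independent lists. They were Ankrd1, a muscle ankyrin-repeat protein, at -1.21 and -1.82, the G protein subunit Gna14 at -1.19 and -1.47, the annexin Anxa3 at -1.13 and -1.11, Gm30873 at -1.43 and -1.63 and Gm41724 at ratios of 0.499 and 0.445. Fads3, a member of the fatty acid desaturase family, followed at ratios of 0.501 and 0.394. When each treatment also had to differ 2-fold from the other control array, 1 gene was lower in both, and against DMSO Anxa3 and Gm41724 differed by -0.78 and -0.66 with Mkl1 siRNA.

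Of the 147 genes higher with Y-27632, 115 were above 0 with Mkl1 siRNA (median 1.23), and of the 26 lower genes 23 were below 0 (median -0.66). In the other direction, 185 of the 208 genes higher with Mkl1 siRNA were above 0 with Y-27632 (median 0.81), but only 112 of the 202 lower genes were below 0 (median -0.08). Across the 11600 genes, which are not independent replicates, the differences had a Pearson r of 0.386 and a Spearman rho of 0.255. The SD of the differences was 0.31 with Y-27632, 0.44 with Mkl1 siRNA and 0.36 between the controls. No gene was at least 2-fold lower with Y-27632 and higher with Mkl1 siRNA, and 11 were higher with Y-27632 and lower with Mkl1 siRNA, where independent lists would share 2.56. Among these were Mgp at 2.07 and -2.40, Ccl11 at 1.45 and -3.57, and Cd34, a sialomucin of progenitor cells, at 1.79 and -1.82. Mgp and Ccl11 were lower with Y-27632 than with control siRNA, by -0.74 and -0.62.

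**Figure D3:**
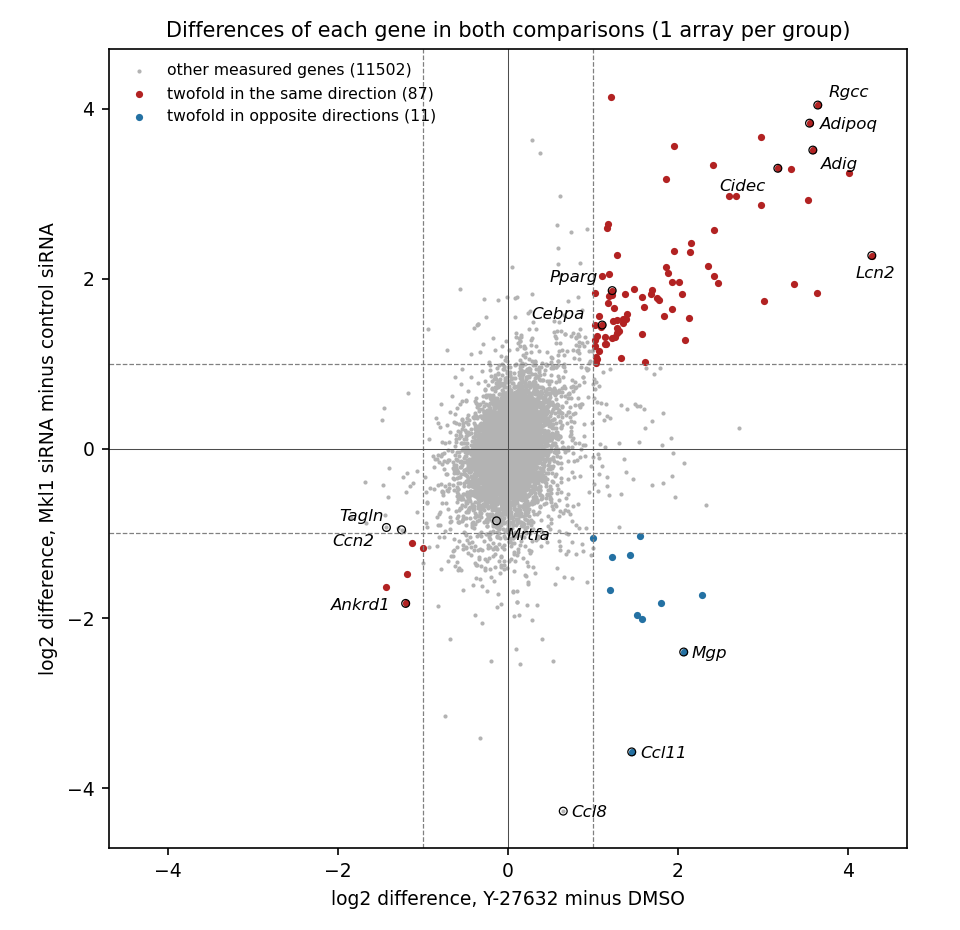
Log2 difference of each of 11600 genes with Y-27632 (horizontal) and with Mkl1 siRNA (vertical), each against its own control array, with dashed lines at 2-fold. The 82 genes higher in both lie at the upper right, and the 11 genes higher with Y-27632 and lower with Mkl1 siRNA at the lower right.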

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

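All tests in this part were chosen after the results they concern were seen, and no difference here was tested against replicates. Scaling between arrays was not tested as an explanation, because the deposited values were already quantile-normalised. Loess and subtracting the median were run only as alternatives in processing.

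In 11 genes at least 2-fold apart in opposite directions in both comparisons, the differences with Y-27632 and then with Mkl1 siRNA, each against its own control, were 1.51 and -1.96 for the phosphatase Acpp, 1.45 and -3.57 for Ccl11, 1.79 and -1.82 for Cd34, 1.22 and -1.28 for Clec14a, 1.55 and -1.03 for Egr2, and 1.57 and -2.01 for the coagulation factor subunit F13a1. They were 1.20 and -1.67 for Il33, 2.07 and -2.40 for Mgp, 2.28 and -1.72 for Saa1, 1.003 and -1.05 for Saa2, and 1.44 and -1.25 for the semaphorin Sema7a. The difference between the comparisons was not tested, and Saa1 and Saa2 were read by probe sets that can bind shared sequence. That the control siRNA and DMSO arrays were already apart is a candidate explanation, and it stays open with 1 array per group. Of the 11 genes, 5 (Acpp, Cd34, Clec14a, Il33 and Saa1) were at least 2-fold apart in opposite directions from both control arrays and 6 were not. Of those 6, Ccl11 and Mgp changed side, at -0.62 and -0.74 with Y-27632 against control siRNA. Saa2, Sema7a, F13a1 and Egr2 kept both directions but fell short of 2-fold. They stood at 0.89, 0.71, 0.40 and 0.55 with Y-27632 against control siRNA. With Mkl1 siRNA against DMSO they stood at -0.94, -0.52, -0.84 and -0.04. Control siRNA stood above DMSO in 10 of the 11, which choosing genes above DMSO and below control siRNA favours. Among those 6 the control arrays differed by 0.11 for Saa2, 0.73 for Sema7a and up to 2.81 for Mgp.

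Among 3386 measured probe sets with no single gene name, which no comparison above used, 91 (2.69%) were at least 2-fold apart with Mkl1 siRNA, above the 65 (1.92%) between the controls. With Y-27632 the number was 40. Among the 11600 named genes, 1.79% were at least 2-fold higher and 1.74% lower with Mkl1 siRNA, so the share was not larger without a gene name. The difference was not tested.

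Mature adipocyte genes were higher in both comparisons. RNA degradation stays open: the 3' minus 5' difference was at most 0.255 for Actb and Gapdh, but reached 1.767 for pyruvate carboxylase, so the control transcripts disagreed. For pyruvate carboxylase the 3' signal was higher by 1.77 with Y-27632 and 2.10 with Mkl1 siRNA. Its 5' signal was not lower, at 0.13 and 0.33. Its shift thus came from a higher 3' signal, not from a loss of 5' signal, and cannot by itself show degradation. A larger share of fat-cell-like cells cannot be told apart from higher expression per cell: members differed unequally (SD 1.204 with Y-27632), but levels in each kind of cell are not measured in bulk RNA. A release of fat cell genes on lower ROCK or MRTF activity may be the biological explanation and was not tested.

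Interferon and mitosis genes were lower with Y-27632 than with DMSO. A high DMSO array is a candidate explanation, since against control siRNA the medians were 0.071 for interferon genes (random range -0.102 to 0.139) and -0.067 for G2 and mitosis genes (random range -0.079 to 0.164). It stays open, because control siRNA was itself below DMSO, by medians of -0.72 and -0.42, and also differs from DMSO by transfection. A low control siRNA array would give the same medians beside a true difference with Y-27632, and these cannot be told apart. With Mkl1 siRNA the interferon median was -0.48 against control siRNA. The Mkl1 siRNA array was also below Y-27632, with a median of -0.576 (random range -0.139 to 0.140), which leaves both control arrays out. As Y-27632 and control siRNA were only 0.071 apart, this adds little to the difference from control siRNA. It also sets a transfected against an untransfected array. Whether the low interferon genes come from the knockdown or from the single Mkl1 siRNA array stays open.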

How the results depend on the processing

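The other control array was an alternative chosen after seeing the data; all others were planned. No paired analysis was possible because each group has 1 array, which also rules out leave-one-out. Of 298 list medians under alternatives, 262 moved by less than the spread of random lists, 35 by more and 1 reversed; of 77 counts, 52 stayed within 1.5 times. Loess and subtracting the median moved no count or list median past these limits, and the Mrtfa difference ran from -0.87 to -0.62. Without the filter on low values the 4 treatment counts were 156, 26, 218 and 207; detection calls were not used here, so what signal over background limits stays unknown. Beyond settings that test fewer genes, the cause was not tested. In the order Y-27632 higher and lower, Mkl1 siRNA higher and lower, the counts were 348, 154, 629 and 686 at 1.5-fold (controls 397 and 475; both higher 177, both lower 54, opposite 51), and 83, 15, 122 and 113 at the 99th percentile of the control difference (both higher 51, opposite 5). With the filter at the 75th percentile, which tests fewer genes, they were 96 and 14 for Y-27632, 129 higher for Mkl1 siRNA, 83 lower between the controls, 52 higher in both and 7 opposite. Requiring 2-fold from the other control too left 98 higher and 10 lower for Y-27632, and 165 higher and 114 lower for Mkl1 siRNA. It left 1 lower in both and 5 opposite.

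With the mean of all probe sets the Y-27632 median was -0.24 for S phase and -0.17 for inflammatory genes. Without probe sets that may bind several transcripts it was -0.39 for smooth muscle, 1.93 for mature adipocyte, 0.13 for cholesterol, -0.23 for focal adhesion and -0.16 for inflammatory genes, and with Mkl1 siRNA -0.30 for MRTF-SRF, 1.93 for mature adipocyte and -0.35 for inhibitors of adipogenesis. Without the filter it was 0.0625 for brown and beige genes (Y-27632) and -0.23 for smooth muscle (Mkl1 siRNA). With the 75th percentile filter it was 0.0487 for immediate early and 1.93 for mature adipocyte genes with Y-27632, and 1.86 for mature adipocyte, -0.91 for cholesterol and 0.14 for S phase genes with Mkl1 siRNA. Against control siRNA the Y-27632 medians were -0.29 for YAP-TAZ, 0.14 for immediate early, 1.52 for mature adipocyte, 0.20 for inhibitors of adipogenesis, -0.18 for cholesterol, -0.11 for TGF-beta, -0.0567 for S phase, -0.0666 for G2 and mitosis, -0.17 for inflammatory, 0.38 for unfolded protein and 0.46 for hypoxia genes, and interferon genes reversed to 0.0715. Against DMSO the Mkl1 siRNA medians were 2.03 for mature adipocyte, 0.46 for fatty acid, -0.27 for cholesterol, -0.19 for S phase, -1.07 for G2 and mitosis, -1.35 for interferon, -0.90 for unfolded protein and -0.52 for hypoxia genes. Among single named genes, 392 values moved little and 15 more. A filter cannot move a gene's difference, yet filters gave 71 and 61 of the 392, and loess and subtracting the median gave 71 each. The mean of all probe sets moved 12 values and left 57, and leaving out probe sets that may bind several transcripts moved 3 and left 61. The other control array was not among these settings, and against it several named genes turned direction or fell short of 2-fold.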

Other observations

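The families in this part were chosen after the values were seen and have no test. The members of the acute phase and lipocalin family were also picked by hand, and include Lcn2, Wfdc21 and Hp, already among the highest genes with Y-27632. Other lipocalins and acute phase proteins were left out, so the count says nothing about such proteins as a class. Of 10 measured, 9 were at least 2-fold above DMSO with Y-27632 (median 2.52). Among them were Lcn2 at 4.28, Wfdc21 at 4.01, Hp at 3.63 and the acid glycoprotein Orm1 at 2.98. Saa3 stood at 2.71, Itih5 at 2.33 and the copper carrier Cp (ceruloplasmin) at 1.40. Against control siRNA, Hp stood at 0.89 and Saa2 at 0.89, short of 2-fold. With Mkl1 siRNA the family was mixed, with 4 at least 2-fold higher, among them Orm1 at 2.86, and Saa1 and Saa2 at least 2-fold lower (median 0.36). Itih5 differed by -0.66 there. Of 6 measured carboxylesterases, 3 were above and 3 below DMSO with Y-27632 (median 0.06), and Ces1f and Ces1d were higher by 2.35 and 1.62, and by 2.15 and 0.95 with Mkl1 siRNA. Of 15 aldehyde dehydrogenases, 8 were above and 7 below DMSO with Y-27632 (median 0.07), and Aldh6a1, an enzyme of valine breakdown, was higher by 1.35 and with Mkl1 siRNA by 1.48.

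With Mkl1 siRNA all 9 measured clade B serpins, intracellular protease inhibitors, were below control siRNA (median -0.60), including Serpinb2 at -3.15, Serpinb9b at -1.96, Serpinb1a at -1.82 and Serpinb6c at -1.19. Of these 9, 8 stood higher with control siRNA than with DMSO, Serpinb1a by 1.44, and against DMSO Serpinb1a and Serpinb6c differed by -0.39 and -0.69. Collagens lay below control siRNA in 23 of 26 cases (median -0.38), or 22 after loess or subtracting the median, with Col1a1 at -1.05, Col4a5 at -1.18 and Col5a2 at -0.82. With Y-27632 the collagen median was 0.05, and the basement membrane collagen Col15a1 was higher by 1.82. Of 21 chemokine ligands, 5 were at least 2-fold lower with Mkl1 siRNA (Ccl2, Ccl7, Ccl8, Ccl11 and Cxcl10), while Cxcl14 was higher by 1.45. Control siRNA stood above DMSO for 4 of the 5 lower ones, all but Cxcl10, and against DMSO Ccl2 and Ccl7 were short of 2-fold at -0.94 and -0.33.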
